A study of Mus musculus with 66 samples.

How the data were processed

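Libraries of 66 samples in 13 groups were made, per the labels' protocols, from 100 to 200 cells sorted into lysis buffer, with a low-input amplification adapted from a single-cell protocol, which counts reads and not molecules. The deposited tables hold whole-number read counts per gene symbol, and no header states how genes were counted. Per the submitters' processing notes, CASAVA, TopHat2, Cufflinks, HTSeq and DESeq2 were used with the genome build mm9, without versions, roles or parameters. The deposited FPKM values, scaled for transcript length and library size, cover the same libraries and were used here only as an alternative scale. Each count table lists 25793 genes and holds 0 immunoglobulin segment or constant genes and 0 mitochondrial genes, so neither was analysed. Total counts per library ran from 1.92 to 11.9 M (mega counts) in the NP-KLH table of 30 libraries and from 1.12 to 9.3 M in the SRBC table of 36. No pair of libraries of a group was a duplicate (chi-square per degree of freedom from 3.676 to 144.7 over genes with at least 20 counts).

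Groups were taken from the labels' cell type, immunization and treatment. The sort gates were NIP-binding CD19-positive CD38-positive GL7-, FAS-, IgM- and IgD-negative for memory cells, NIP-binding CD138-positive B220-low for spleen plasma cells, and the same with Gr1-negative for marrow plasma cells. The labels do not explain the 2 numbers in each library title. The first was used as a batch term, called the set; the full number was tried as a block.

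Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values scaling, filterByExpr on group, quasi-likelihood fits with robust estimation and a model of group and set, Benjamini-Hochberg adjusted p under 0.05. Separate fits were made for the 12 NP libraries (9774 genes), the 18 libraries of sets 3 and 4 (11715 genes) and the 36 SRBC libraries (10084 genes); the residual degrees of freedom were 9, 12 and 29, and the common biological coefficients of variation 0.653, 1.01 and 0.354. There were 16 comparisons of groups and 2 tests of a difference in treatment effect between subsets. Gene lists, 25 in number, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; list members were also adjusted over the list alone. An estimated correlation was the alternative. Lists that no paragraph mentions for a comparison are in the tables with their values.

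Genes were named by a rule also fixed then. For each comparison it took up to 8 genes with the largest rise and 8 with the largest fall among those that passed, had an average logCPM of at least 4 and had 1 direction in every set holding both groups. Of each list described it took up to 4 members with the smallest adjusted p, or 2 with the largest change where none passed. Cd38, Fas, Sdc1, Ptprc, Cd19, Il9r, Bcl6, Prdm1, Aicda, Ccr6, Bcl2, S1pr2 and Ccnd2 were always eligible. Immunoglobulin segments and genes with Gm, Rik, Mir, Snor or mt- names were left out of the first part: 12 of 338 eligible genes for GC-MP against GC-MPP after NP-KLH, 38 of 998 after SRBC, and at most 57 of 1373 elsewhere. The text names a selection of those genes and says where another was named after its values were seen. Folds against 0 counts are lower bounds against a floor of 3 counts over the group; floors cover counting error only, since reads are not independent molecules.

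Alternatives were RLE scaling, no filter or an average logCPM of at least 4, DESeq2 1.42.0, limma on log2 of FPKM plus 1 (with a minimum mean of 1, no minimum, or a pseudocount of 0.1), no set term, the replicate block, libraries summed by group and set, each set alone, only the libraries compared, and each library left out. For signatures the top 200 genes, lists without cell cycle genes, RLE and an estimated correlation were tried. Leaving out both memory libraries of set 4, and the memory list without plasma cell genes, were added after the data had been seen. Shared PBS controls were checked with 20 simulations and with the controls split.

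The tests were checked on simulated data drawn from the real means and library sizes with 100 genes changed by a log2 fold of 1 and 100 by 2. edgeR recovered 33% and 75% in the NP comparison, 67% and 100% after SRBC, 80% and 100% for anti-IL-9 against PBS in GC-MP, 2% and 17% for memory against spleen plasma cells, 1% and 24% for bone marrow against spleen plasma cells, 0% and 2% for memory against GC-MPP and 0% and 0% for NIP-binding GC-MP against GC-MPP. At most 3.85% of its calls were false, against 83.3%, 74.3% and 48.7% for DESeq2 in the NIP-binding, memory against GC-MPP and memory against spleen plasma comparisons. The reference annotation at hand is of another build (GRCm38) and was used for names, transcripts and neighbouring genes only.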

Results

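Polyadenylated RNA was sequenced from 66 samples of 100 to 200 sorted mouse cells, in 13 groups. The mice carried Fucci, a cell cycle reporter in which the mKO2 protein accumulates in G1. Spleen germinal centre (GC) B cells were sorted as mKO2-high CD38-positive cells, called GC-MP here, and as mKO2-low CD38-negative cells, called GC-MPP. Both were GL7- and FAS-positive. After NP-KLH with LPS and alum, collected on day 13, there were 6 libraries each of GC-MP and GC-MPP, and 2 each of the cells that also bound the hapten NIP. The same immunization gave 4 libraries of NIP-binding memory B cells, 4 of spleen plasma cells and 6 of bone marrow plasma cells. After sheep red blood cells (SRBC), collected on day 8, GC-MP and GC-MPP cells came from mice given PBS, IL-9 (1.33 µg per mouse) or anti-IL-9 (200 µg per mouse) 24 h before collection, with 6 libraries per group.

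The first of 2 unexplained numbers in each title, the set, was taken as a batch. NP libraries fall in sets 1 and 2, and NIP-binding, memory and plasma cells in sets 3 and 4. SRBC libraries have sets 1 and 2 of their own. Total counts per library, in units of M (mega counts), ran from 7.14 to 11.9 M in the NP groups, from 3.56 to 4.59 M in the NIP-binding GC groups, from 2.49 to 4.82 M in memory cells, from 2.13 to 3.67 M in spleen plasma cells and from 1.92 to 2.95 M in bone marrow plasma cells. In the SRBC groups they ran from 1.12 to 9.3 M, with 1.12 to 1.75 M in the GC-MP libraries given PBS in set 2 and 1.4 to 3.73 M in the GC-MPP libraries given anti-IL-9 in set 1. The 10 most abundant genes took 19.5% ± 1.09 (SD, n = 4) of the counts in spleen plasma cells and 9.34% ± 0.562 (SD, n = 4) in memory cells. Levels are CPM (counts scaled to the size of each library) with the SD between libraries, fold changes are log2 with their standard error (SE), and "passed" means a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test with set as a term. Where no number of libraries is given beside a gene that passed and was not named after its values were seen, each library of its group lay on 1 side of each library of the other. The p-values measure the spread between libraries, which may be in part technical, since the labels do not say whether libraries of 1 set come from separate mice.

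The first comparison asked how GC-MP cells differ from GC-MPP cells after NP-KLH. Sell, which encodes the homing receptor L-selectin, rose from 3.45 ± 4.11 CPM in GC-MPP to 224 ± 67.3 CPM in GC-MP (SD, n = 6 each, log2 fold change 6.17, SE 0.48, adjusted p = 5.38e-07). S1pr1, the receptor that guides egress into blood, rose from 2.76 ± 3.6 to 144 ± 34.9 CPM (5.86, SE 0.51, adjusted p = 1.51e-06), and Klf2, a transcription factor that drives both genes, from 11.4 ± 10.2 to 190 ± 36.1 CPM (4.15, SE 0.46, adjusted p = 2.35e-05). The antiapoptotic gene Bcl2 rose from 7.84 ± 3.67 to 79.7 ± 24.3 CPM (3.37, SE 0.44, adjusted p = 0.000134), and Cd38, a sort marker, from 31.1 ± 11.5 to 228 ± 78 CPM (2.90, SE 0.26, adjusted p = 1.51e-06). For these 5 genes each of the 6 GC-MP libraries lay above each GC-MPP library. Il9r, the receptor for IL-9, rose from 8.96 ± 13.9 to 59.9 ± 39 CPM (3.21, SE 0.60, adjusted p = 0.0044), with 3 of 6 GC-MP libraries above each GC-MPP library.

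Aicda and S1pr2, genes of the germinal centre reaction, were lower in GC-MP but remained abundant. Aicda, the deaminase of somatic hypermutation, fell from 728 ± 81.1 to 368 ± 54.5 CPM (-0.99, SE 0.14, adjusted p = 0.000201). S1pr2, which confines B cells to the follicle centre, fell from 509 ± 66.6 to 253 ± 53 CPM (-1.0, SE 0.16, adjusted p = 0.00103). For both genes each of the 6 GC-MP libraries was below each GC-MPP library. Fas (-1.07, adjusted p = 0.00407), the GC factor Basp1 (-1.43, adjusted p = 0.000235, 3 of 6 libraries below) and Bach2, a repressor of plasma cell fate (-1.0, adjusted p = 0.00109), also fell. Bcl6, the master repressor of the GC program, had a log2 fold change of -0.80 and did not pass (adjusted p = 0.23), nor did Cd19 (0.18, adjusted p = 0.595). Ccnd2, a G1 cyclin, stood 2.35 higher without passing (adjusted p = 0.1), and passed when GC-MPP library 2-3 was left out (adjusted p = 0.0146). The chemokine receptor Ccr6, a marker of memory precursors, passed at 2.79 (adjusted p = 0.0468, 5 of 6 libraries above) and with 1 library left out it passed only without GC-MP library 2-3 or GC-MPP library 2-2. Its adjusted p was 0.09, 0.114, 0.0641, 0.0978 and 0.125 without GC-MP library 1-1, 1-2, 1-3, 2-1 and 2-2, and 0.0902, 0.0507, 0.065, 0.0693 and 0.0597 without GC-MPP library 1-1, 1-2, 1-3, 2-1 and 2-3.

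**Figure D1:**
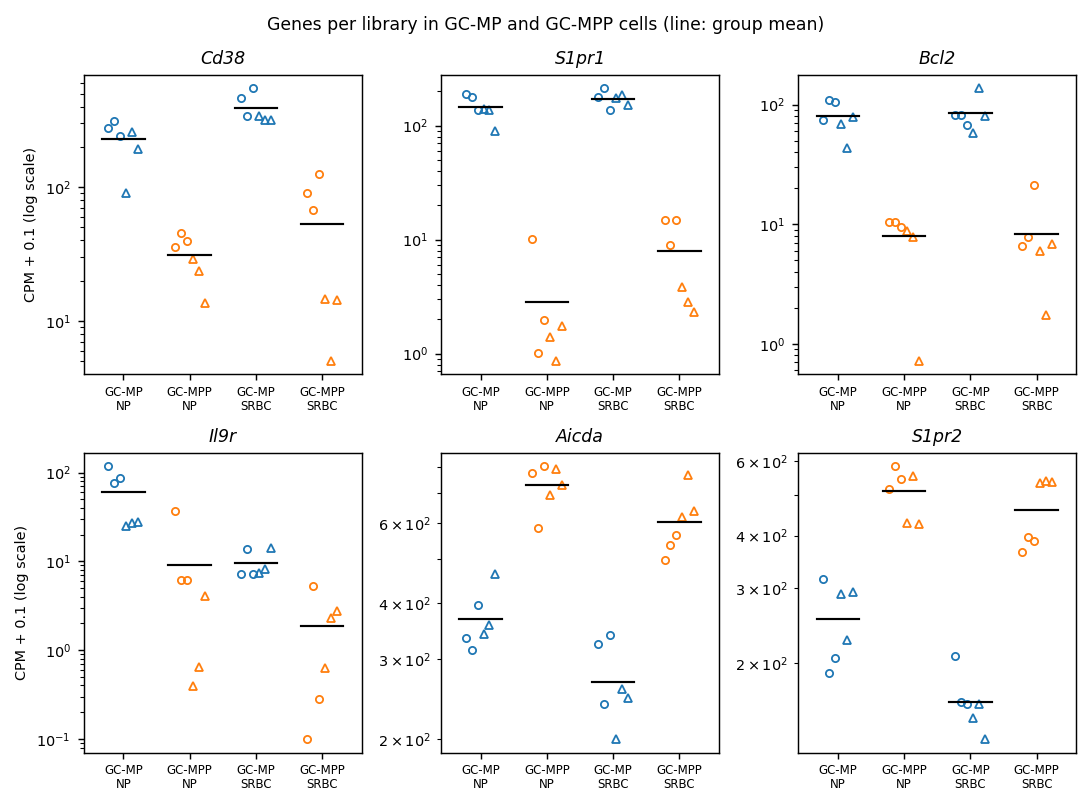
CPM plus 0.1 on a log scale of 6 genes in each GC-MP and GC-MPP library after NP-KLH (6 and 6 libraries) and after SRBC with PBS (6 and 6). Points are libraries, circles for set 1 and triangles for set 2, and lines are group means; Bcl2 averaged 79.7 and 7.84 CPM in the NP groups and 84.3 and 8.26 CPM in the SRBC groups.

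Gene by gene, 224 genes rose and 164 fell among 9774 tested. The total was 247 without the set term, 213 with all 30 libraries of the table in the fit (139 shared) and 0 with libraries summed by group and set, which leaves few residual degrees of freedom. In set 1 alone 77 rose and 34 fell, and in set 2 alone 29 rose and 3 fell. Of 17 measured genes on a memory B cell list, 12 rose, 1 fell and 4 did not pass (12 and 2 adjusted over the list alone). The median log2 fold change was 2.98 (camera adjusted p = 4.45e-26), and Gpr183, the oxysterol receptor that positions B cells at the follicle edge, rose by 3.76 (adjusted p = 2.89e-05). Of 21 genes of the germinal centre program 9 fell and 12 did not pass (14 lower adjusted over the list alone, median -0.75, adjusted p = 1.03e-12), among them Mybl1 (-2.67, adjusted p = 0.0151, 4 of 6 libraries below). Cells were sorted by mKO2, which accumulates in G1, so differences in S phase and cell cycle exit lists between GC-MP and GC-MPP, here and below, are expected from the gate. The S phase list had 9 of 36 lower and 27 not passing (15 adjusted over the list alone, median -0.69, adjusted p = 7.49e-15). The replication helicase genes Mcm6 and Mcm2 fell by 1.01 and 0.89. In contrast 5 of 23 genes of cell cycle exit rose and 18 did not pass (5 higher and 1 lower adjusted over the list alone, median 0.58, adjusted p = 0.000105), with Sesn1 at 2.08 and Txnip, a brake on glucose uptake, at 1.16. The G2 and M phase list had no common direction (1 higher, 1 lower, 33 not passing, adjusted p = 0.527, with a median of -0.06 against an upward test statistic).

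Interferon response genes rose as a group, with 6 of 27 higher, 21 not passing and 15 adjusted over the list alone (median 1.28, adjusted p = 4.74e-12). The RNA sensor Ddx58 rose by 3.39 and Rtp4 by 6.05. The IL-9 and gamma-chain signalling list had 2 of 23 higher, Bcl2 and Il9r, and 21 not passing (6 adjusted over the list alone, median 0.42, adjusted p = 0.00112). Migration and adhesion receptors moved both ways, with 11 higher, 3 lower and 13 not passing (12 and 4 adjusted over the list alone, median 0.44, adjusted p = 3.75e-10), and the integrin gene Itga4 rose by 1.58. Of 17 naive follicular genes 8 rose, 1 fell and 8 did not pass (9 and 1 adjusted over the list alone, median 0.62, adjusted p = 6.89e-22), including Cd1d1 at 6.12, which encodes a lipid-presenting molecule. In antigen presentation 4 of 22 genes rose, 1 fell and 17 did not pass (5 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.00691), and B2m and H2-K1, both parts of MHC class I, rose by 1.11 and 1.36 (6 and 3 of 6 libraries above). Cytosolic ribosomal protein genes stood slightly higher (2 higher and 75 not passing of 77, median 0.24, adjusted p = 9.62e-06), while the oxidative phosphorylation list (0 higher, 2 lower, 52 not passing, median -0.16, adjusted p = 0.00619) and the unfolded protein response list (0 higher, 3 lower, 39 not passing, median -0.20, adjusted p = 0.00831) stood lower. With an estimated correlation these last lists did not pass: adjusted p = 0.447 for antigen presentation, ribosomal proteins and oxidative phosphorylation, and adjusted p = 0.0776 for the unfolded protein response.

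The plasma cell list showed no common direction (3 higher, 3 lower, 10 not passing, adjusted p = 0.96), nor did light zone activation (adjusted p = 0.398), apoptosis and survival (adjusted p = 0.118), glycolysis (adjusted p = 0.257), B cell identity (adjusted p = 0.527), immediate early genes (adjusted p = 0.905) or MYC and ribosome biogenesis (adjusted p = 0.599). Igj, the immunoglobulin joining chain, fell by 1.2 (adjusted p = 0.0141, 4 of 6 libraries below) and had adjusted p = 0.0544 without GC-MP library 1-2. The proapoptotic gene Bmf fell by 1.44 (adjusted p = 0.00501). Of 3 measured T cell markers 1 rose, 1 fell and 1 did not pass (adjusted p = 0.907). The total of 388 genes became 241 (156 higher, 85 lower) without GC-MP library 1-1.

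In NIP-binding cells, with 2 libraries per group and set 3 alone, 25 genes rose and 0 fell by edgeR (605 at an unadjusted p under 0.05). DESeq2 called 130 higher and 21 lower, with 83.3% false calls on simulated data, and limma on FPKM called 42 higher and 9 lower. Plac8, a gene of resting lymphocytes, rose from 0.701 ± 0.72 to 398 ± 21.1 CPM (SD, n = 2, 9.09, SE 1.08, adjusted p = 4.83e-05). B2m rose by 1.47 (adjusted p = 0.000195). Bcl2 rose from 6.47 ± 0.876 to 86.1 ± 44.7 CPM (3.73, SE 0.56, adjusted p = 0.000605), and Cd1d1 from 0 counts to 54.5 ± 3.84 CPM, at least 185-fold higher against a floor of 3 counts over the group (adjusted p = 0.000605). Without GC-MPP library 3-2 Bcl2 and Cd1d1 had adjusted p = 0.081 and 0.0561 and 7 genes passed in total. The lone remaining sample is then assumed to vary like the other groups. The 25 calls became 5 with only the libraries compared in the fit and 1 with libraries summed by group and set. Il9r stood at 79 ± 1.75 against 28.5 ± 5.77 CPM (1.47, SE 1.40, adjusted p = 1), Cd38 at 181 ± 43.8 against 30 ± 11 CPM (2.59, SE 1.49, adjusted p = 0.996) and S1pr2 at 99.3 ± 44.1 against 382 ± 36.4 CPM (-1.94, SE 0.68, adjusted p = 0.649), so none of the 3 passed although both GC-MP libraries lay on 1 side of both GC-MPP libraries.

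As lists, the memory B cell genes (median 2.61, adjusted p = 6.8e-08), cell cycle exit (1.06, adjusted p = 0.000155) and interferon response (1.46, adjusted p = 1.41e-05) stood higher in NIP-binding GC-MP cells, and the germinal centre program (-0.91, adjusted p = 8.84e-05) and S phase genes (-0.997, adjusted p = 1.41e-05) lower. Granulocyte and macrophage markers stood higher there too (0 of 15 passing, median 3.17, adjusted p = 1.19e-06), with Emr1, the F4/80 gene, at 69.9 ± 4.92 against 0.393 CPM (7.34, SE 2.32, adjusted p = 0.452). Dendritic and NK cell markers likewise stood higher (0 of 8 passing, 2.28, adjusted p = 0.0077). Erythroid and megakaryocyte markers (adjusted p = 0.123) and stroma and endothelium markers (adjusted p = 0.694) did not differ as lists.

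After SRBC, GC-MP and GC-MPP cells of the PBS mice were compared to ask whether the difference holds for another antigen and day. Plac8 rose from 5.73 ± 4.17 to 507 ± 172 CPM (SD, n = 6 each, 6.46, SE 0.71, adjusted p = 1.51e-07) and S1pr1 from 7.86 ± 5.83 to 173 ± 26.8 CPM (4.55, SE 0.45, adjusted p = 2.5e-08). Bcl2 rose from 8.26 ± 6.66 to 84.3 ± 27.8 CPM (3.29, SE 0.41, adjusted p = 2.15e-07), and Cd38 from 52.8 ± 49.2 to 387 ± 95.2 CPM (3.31, SE 0.52, adjusted p = 3.45e-05). Il9r rose from 1.79 ± 1.97 to 9.56 ± 3.37 CPM (2.35, SE 0.67, adjusted p = 0.0138). Aicda fell from 604 ± 94.4 to 268 ± 53.7 CPM (-1.17, SE 0.17, adjusted p = 3.02e-06) and S1pr2 from 460 ± 83.8 to 162 ± 25.4 CPM (-1.53, SE 0.19, adjusted p = 1.14e-07). All 6 GC-MP libraries lay on 1 side of all GC-MPP libraries for these 7 genes. Ccr6 (2.84, adjusted p = 0.00244), Ccnd2 (2.18, adjusted p = 0.0148) and Ccr7, the receptor for T zone chemokines (3.83, adjusted p = 2.98e-05), rose. Fas (-1.13, adjusted p = 0.000505) and the GC transcription factor Mef2b (-1.26, adjusted p = 1.45e-07) fell, and Bcl6 did not pass (-0.59, adjusted p = 0.321).

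Among 10084 genes, 668 rose and 613 fell, and with libraries summed by group and set 320 genes passed. In set 1 alone 172 rose and 83 fell, and set 2 alone gave 1239 calls, of which 47% were higher. The S phase list had 33 of 37 lower and 4 not passing (36 adjusted over the list alone, median -1.21, adjusted p = 2.35e-43). Cdc45l, a replication fork gene, fell by 2.02, Rad51 by 1.80 and Rrm2, which supplies deoxynucleotides, by 1.48. Genes of mitosis split instead (9 higher, 5 lower, 22 not passing, adjusted p = 0.218): Cdc20, which activates the anaphase complex, rose by 2.49 and Ccnb2 by 1.90, while Top2a fell by 1.16 (3 of 6 libraries below). Of 23 genes of cell cycle exit 11 rose, 2 fell and 10 did not pass (13 and 2 adjusted over the list alone, median 0.81, adjusted p = 9.57e-08), including Btg1 at 1.07 and Txnip at 1.58. Memory B cell genes (12 higher, 2 lower, 3 not passing, 13 and 2 adjusted over the list alone, median 2.35, adjusted p = 9.47e-13), the germinal centre program (1 higher, 13 lower, 7 not passing, 1 and 14 adjusted over the list alone, median -0.97, adjusted p = 8.48e-13) and naive follicular genes (11 higher, 1 lower, 5 not passing, 11 and 1 adjusted over the list alone, median 0.67, adjusted p = 6.4e-10) moved as after NP-KLH.

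Interferon response genes rose (12 of 33, 21 not passing, 15 adjusted over the list alone, median 0.82, adjusted p = 9.57e-08), with Ddx58 at 2.04 and Samd9l at 1.19. Migration receptors had 13 higher, 3 lower and 10 not passing (14 and 4 adjusted over the list alone, median 0.95, adjusted p = 6.84e-05), and Sell rose by 4.65. Metabolic and secretory lists fell: oxidative phosphorylation (11 of 54 lower, 13 adjusted over the list alone, median -0.23, adjusted p = 2.93e-05), glycolysis (1 higher, 5 lower, 14 not passing, median -0.33, adjusted p = 0.00918, Gapdh -0.82 with 5 of 6 libraries below) and the unfolded protein response (1 higher, 9 lower, 33 not passing, median -0.37, adjusted p = 2.93e-05). In gamma-chain signalling 3 rose, 2 fell and 21 did not pass (5 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.0256, and adjusted p = 0.0669 with an estimated correlation). The shared receptor chain Il2rg rose by 0.72 and Il21r, the IL-21 receptor, fell by 0.48 (3 of 6 libraries below). Ribosomal protein genes (10 higher, 2 lower, median 0.19, adjusted p = 0.002) and the MYC list (0 higher, 5 lower, median -0.17, adjusted p = 0.035) had adjusted p = 0.648 and 0.139 with an estimated correlation. Granulocyte and macrophage markers moved with GC-MP (4 of 8 higher, 4 not passing, median 2.95, adjusted p = 0.00594, and adjusted p = 0.22 with an estimated correlation). Lyz1, a lysozyme gene, was at 6.61 ± 8.95 CPM against 0 counts, at least 37.4-fold higher (adjusted p = 0.0051, 5 of 6 libraries above). C1qa rose by 3.94 (adjusted p = 0.00686, 4 of 6 libraries above), and C1qb rose by 3.21 (adjusted p = 0.0182, 4 of 6 above) but did not pass without GC-MP library 2-2 (adjusted p = 0.125). Tyrobp, an adaptor of myeloid receptors, rose by 4.18 (adjusted p = 2.71e-07), and Hck, a myeloid and B cell kinase, by 5.13 (adjusted p = 1.5e-05).

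Most genes that passed after NP-KLH also passed after SRBC. Of 222 genes higher in GC-MP after NP-KLH and measured after SRBC, 179 also rose there, where 14.2 would be shared if calls were independent, and of 164 lower 102 also fell (10.6 if independent). None of the 222 and 164 passed in the opposite direction. As a signature, the NP genes had a median of 1.58 and -0.65 after SRBC (camera adjusted p = 2.24e-104 and 1.84e-51). Of 24 genes higher in NIP-binding GC-MP cells, 23 also rose after SRBC (1.61 if independent). The log2 fold changes of NP-KLH and SRBC correlated across 9427 genes with r = 0.597 and rho = 0.455. Genes are not independent replicates.

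**Figure D2:**
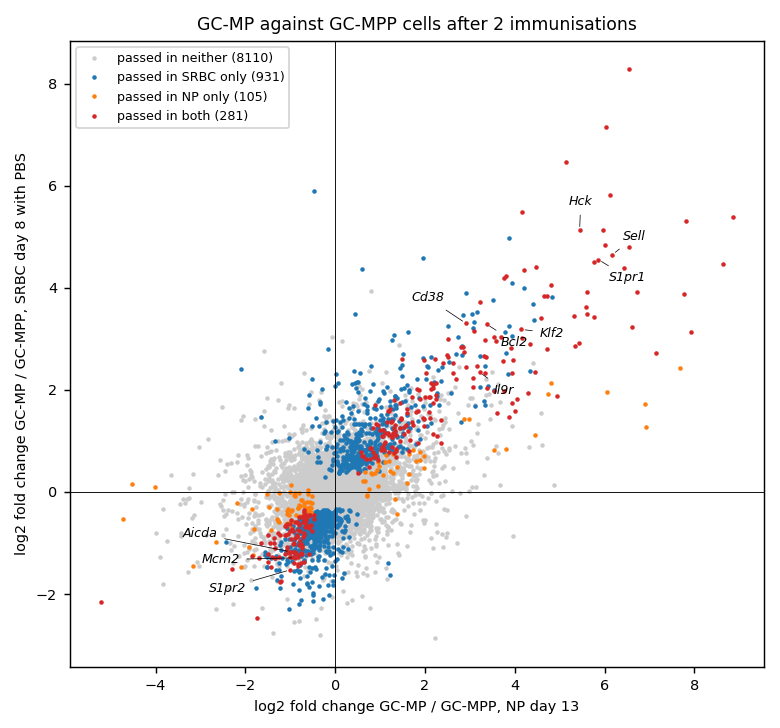
The log2 fold change of GC-MP over GC-MPP after NP-KLH (x axis) against that after SRBC with PBS (y axis), 1 point per gene measured in both (9427 genes), coloured by whether it passed an adjusted p of 0.05 in 1 or both tests. No gene that passed in both had opposite signs; 10 genes named in the text are marked.

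NIP-binding memory B cells were compared with NIP-binding GC cells to place them against the germinal centre. S1pr2 fell from 382 ± 36.4 CPM in GC-MPP to 1.84 ± 1.11 CPM in memory cells (SD, n = 2 and 4, -7.85, SE 0.70, adjusted p = 7.35e-08), and Mef2b fell by 4.01 (adjusted p = 0.000129). Bcl2 rose from 6.47 ± 0.876 to 186 ± 50.6 CPM (4.73, SE 0.57, adjusted p = 8.72e-06). Plac8 rose by 10.40 (adjusted p = 2.11e-06), and Cd1d1 was at 97 ± 16.5 CPM against 0 counts, at least 329-fold higher (adjusted p = 9.58e-05). Igj rose from 419 ± 15.6 to 6337 ± 1960 CPM (3.56, SE 0.20, adjusted p = 4.56e-12), and Prdm1, the regulator of plasma cell fate, was at 6.31 ± 4.66 CPM against 0 counts, at least 21.4-fold higher (adjusted p = 0.000495). All 4 memory libraries lay on 1 side of both GC-MPP libraries for these 7 genes. Il9r averaged 35.7 ± 42.4 CPM in memory and 28.5 ± 5.77 CPM in GC-MPP cells (-0.40, SE 1.35, adjusted p = 0.998), with 1 memory library above and 3 below both GC-MPP libraries.

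Against GC-MPP 86 genes rose and 38 fell in memory. Only the libraries compared gave 9 calls (7 shared) and summed libraries 14 (14 shared). The germinal centre program (5 of 22 lower, 17 not passing, 10 adjusted over the list alone, median -3.22, adjusted p = 1.43e-13) and S phase genes (8 of 36 lower, 28 not passing, 19 adjusted over the list alone, median -2.79, adjusted p = 3.44e-25) fell, with Rrm2 at -8.42. Plasma cell genes rose (7 higher, 1 lower, 16 not passing, 14 and 1 adjusted over the list alone, median 2.40, adjusted p = 9.04e-11), among them Ly6c2 at 5.32. Memory B cell genes (2 higher, 16 not passing, 5 adjusted over the list alone, median 3.09, adjusted p = 2.68e-07), gamma-chain signalling (1 higher, 28 not passing, 6 adjusted over the list alone, median 0.86, adjusted p = 0.00108) and B2m (2.26, adjusted p = 4.98e-08) were higher. Migration receptors (median 1.65, adjusted p = 0.00229), antigen presentation (0.30, adjusted p = 0.0104) and the unfolded protein response (0.38, adjusted p = 0.0484) had adjusted p = 0.145, 0.179 and 0.138 with an estimated correlation. Sdc1, the CD138 gene (6.09, adjusted p = 0.00175), Ccnd2 (4.60, adjusted p = 0.00589) and Xbp1, a driver of secretion (1.25, adjusted p = 0.016), passed. Without GC-MPP library 3-1 their adjusted p were 0.0919, 0.127 and 0.326, and without 3-2 they were 0.0623, 0.169 and 0.0567. The count of 124 became 55 without GC-MPP library 3-1 and 30 without 3-2. On FPKM by limma 38.3% of calls were higher, against 69.4% here, with the median of all genes at -0.211. Set 3 alone gave 198 calls (103 shared).

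Against GC-MP 4 genes rose and 5 fell in memory. Recovery, not simulated here, was 2% at a log2 fold of 2 against GC-MPP, so few calls do not show likeness. Igj rose from 256 ± 29.7 to 6337 ± 1960 CPM (SD, n = 2 and 4, 4.28, SE 0.21, adjusted p = 1.4e-13), and Xbp1 from 111 ± 21.7 to 384 ± 107 CPM (1.62, SE 0.28, adjusted p = 0.00597). S1pr2 (-5.91, adjusted p = 1.01e-05), Dmwd (-7.21, adjusted p = 5.82e-06) and Asns (-5.96, adjusted p = 4.68e-05) fell. Sdc1 (5.68, adjusted p = 0.0119), Ly6c2 (5.22, adjusted p = 0.000387), Rrm2 (-7.77, adjusted p = 0.0183) and Nmral1 (-4.04, adjusted p = 0.0042) completed the list. Without GC-MP library 3-1 Xbp1, Sdc1 and Ly6c2 had adjusted p = 0.326, 0.411 and 0.0834. Without 3-2 Xbp1, Sdc1 and Nmral1 had 0.0525, 0.414 and 0.177. Rrm2 had 0.109 and 0.0613 without GC-MP library 3-1 and 3-2, and 0.0659 and 0.0612 without memory library 3-1 and 3-2. Bcl2 (1.0, adjusted p = 0.688) and Il9r (-1.87, adjusted p = 0.966) did not pass. As lists, plasma cell genes stood higher (4 of 24, 10 adjusted over the list alone, median 1.31, adjusted p = 1.22e-16) and S phase (median -1.64, adjusted p = 2.85e-18) and germinal centre genes (median -1.72, adjusted p = 1.72e-08) lower, while memory B cell genes did not pass (0 of 18, adjusted p = 0.287). Granulocyte and macrophage markers stood lower (0 of 15 passing, median -1.98, adjusted p = 0.00938, and 0.216 with an estimated correlation). The 9 calls became 5 without GC-MP library 3-1 and 17 without memory library 3-2. On FPKM by limma 9.43% of 53 calls were higher, against 44.4% here, with the median of all genes at -0.232. Set 3 alone gave 30 calls and held all 9, only the libraries compared gave 2 and summed libraries 4.

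Genes higher in memory than GC-MPP cells were then read in the separate NP libraries. Both contrasts set CD38-positive against CD38-negative GC-MPP cells, so the gates alone can give a shared direction. Of 86 such genes 76 were measured. Their median log2 fold change of GC-MP over GC-MPP was 1.67, 94.7% were positive, 42 rose and 1 fell (camera adjusted p = 7.8e-83). Of 38 genes lower in memory 37 were measured, with a median of -0.75 and 9 lower (adjusted p = 1.76e-16). Genes higher in spleen plasma cells than in GC-MPP cells had a median of 0.24 (333 measured, 44 higher, 6 lower, adjusted p = 1.75e-11), and those lower had -0.15 (272 measured, 37 lower, 16 higher, adjusted p = 0.000329). The memory list shares many genes with the plasma list, and its 12 measured genes not passing there had a median of 1.37, a check chosen afterwards.

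Spleen plasma cells differed from GC-MPP cells by the genes of antibody secretion. Igj rose from 419 ± 15.6 to 116800 ± 16500 CPM (SD, n = 2 and 4, 7.64, SE 0.25, adjusted p = 6.08e-18) and Xbp1 from 144 ± 39.1 to 5115 ± 1340 CPM (4.94, SE 0.33, adjusted p = 1.33e-10). Prdm1 was at 136 ± 25 CPM against 0 counts, at least 462-fold higher (adjusted p = 3.51e-07). Cd19, the B cell coreceptor, fell from 1175 ± 20.3 to 68.2 ± 47.7 CPM (-3.82, SE 0.50, adjusted p = 8.43e-06). Spib (-5.25, adjusted p = 7.63e-07) and Bach2 (-6.31, adjusted p = 4e-05), both factors of the mature B cell state, fell, as did the MHC class II gene H2-Ab1 (-2.23, adjusted p = 3.59e-06), while B2m rose by 4.41 (adjusted p = 2.53e-13). All 4 plasma cell libraries lay on 1 side of both GC-MPP libraries for these 8 genes. In total 427 genes rose and 280 fell. Of 44 unfolded protein response genes 31 rose and 13 did not pass (37 adjusted over the list alone, median 3.17, adjusted p = 1.89e-41), with Ssr4, part of the endoplasmic reticulum translocon, at 5.76. Of 26 B cell identity genes 17 fell, 1 rose and 8 did not pass (19 and 1 adjusted over the list alone, median -2.54, adjusted p = 4.13e-19).

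Il9r was nearly silent in spleen plasma cells, at 0.868 ± 1.14 CPM (SD, n = 4), against 79 ± 1.75 CPM in NIP-binding GC-MP cells (SD, n = 2, -7.21, SE 1.47, adjusted p = 0.00236) and 28.5 ± 5.77 CPM in GC-MPP cells (-5.74, SE 1.43, adjusted p = 0.0117, and adjusted p = 0.0531 without GC-MPP library 3-1). All 4 libraries were below. Against GC-MP cells 314 genes rose and 286 fell in spleen plasma cells. Igj rose by 8.35 (adjusted p = 1.39e-18), Xbp1 by 5.31 (adjusted p = 5.58e-11) and Bach2 fell by 4.93 (adjusted p = 0.000727). Memory B cell genes (5 of 18 lower, 13 not passing, median -2.21, adjusted p = 2.72e-06) and naive follicular genes (9 of 17 lower, 8 not passing, median -3.12, adjusted p = 1.68e-13) fell, and 34 of 44 unfolded protein response genes rose (36 adjusted over the list alone, median 3.15, adjusted p = 1.3e-50). Granulocyte and macrophage markers were also lower than in GC-MP (8 of 15, 7 not passing, 10 adjusted over the list alone, median -5.64, adjusted p = 7.71e-09), with C1qa at -6.97 (adjusted p = 0.000709). The 707 calls against GC-MPP became 420 without GC-MPP library 3-1 and 352 without 3-2, and the 600 against GC-MP became 285 without GC-MP library 3-1 and 274 without 3-2. On FPKM by limma 16% and 13.1% of calls were higher, against 60.4% and 52.3% here, with the median of all genes at -0.875 and -0.936. Set 3 alone, which holds 1 spleen plasma cell library, gave 606 and 453 calls, and summed libraries gave 330 and 219.

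**Figure D3:**
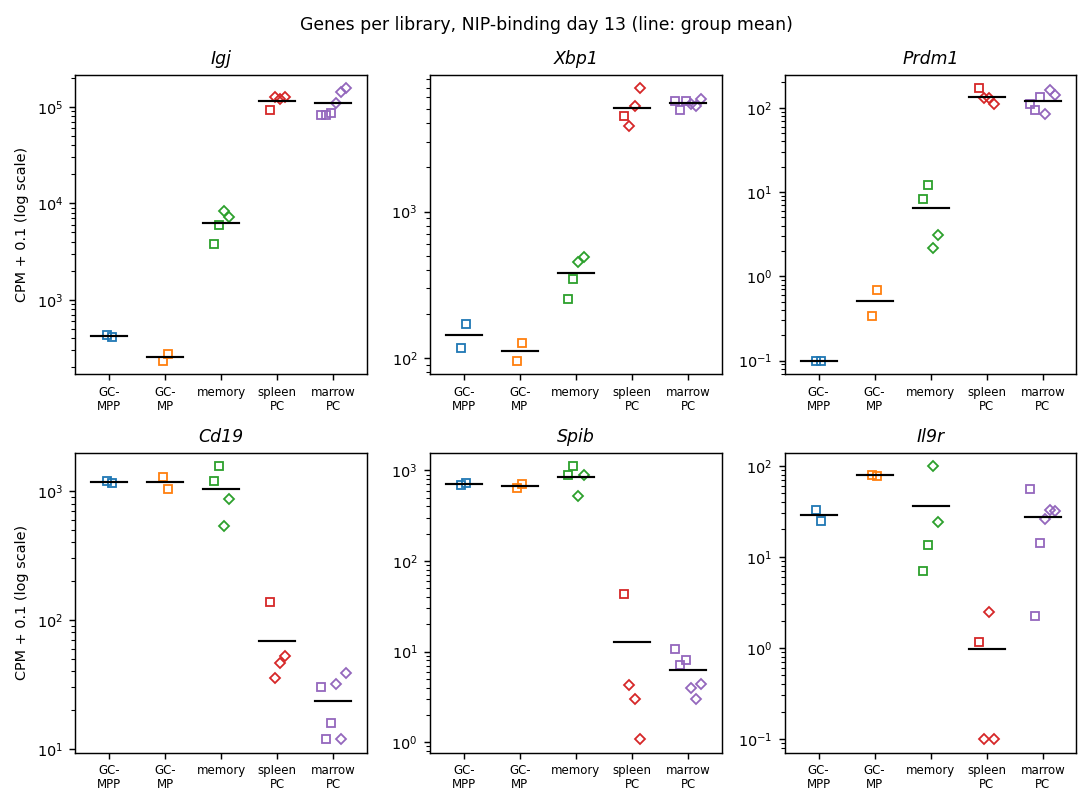
CPM plus 0.1 on a log scale of 6 genes in NIP-binding GC-MPP (2 libraries), GC-MP (2), memory (4), spleen plasma (4) and bone marrow plasma cells (6). Points are libraries, squares for set 3 and diamonds for set 4, and lines are group means; Igj averaged 419 CPM in GC-MPP, 6337 CPM in memory and 116800 CPM in spleen plasma cells.

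Memory and spleen plasma cells are the alternative products of the reaction, and 655 genes were higher and 716 lower in memory. Spib stood at 853 ± 244 against 12.8 ± 20.3 CPM (SD, n = 4 each, 6.49, SE 0.56, adjusted p = 6.89e-09) and Bach2 at 155 ± 60.7 against 2.39 ± 1.23 CPM (6.00, SE 0.79, adjusted p = 5.13e-06). Il9r stood at 35.7 ± 42.4 against 0.868 ± 1.14 CPM (5.33, SE 1.24, adjusted p = 0.00453), with all 4 memory libraries above. Cd19 (3.85, adjusted p = 4.56e-07), Cxcr5, which draws cells into follicles (6.08, adjusted p = 1.22e-06), S1pr1 (5.55, adjusted p = 0.00259) and Btg1 (5.18, adjusted p = 5.75e-07) were higher in memory. Igj (-4.08, adjusted p = 1.49e-16), Xbp1 (-3.69, adjusted p = 5.7e-12), Prdm1 (-4.65, adjusted p = 4.76e-06), Sdc1 (-4.09, adjusted p = 4.54e-05) and the proliferation gene Mki67 (-7.34, adjusted p = 0.000658) were lower. Cd38 was higher by 4.42 (adjusted p = 0.0161) and had adjusted p = 0.0526 without spleen plasma library 4-3. B cell identity genes had 20 of 26 higher and 6 not passing (median 3.10, adjusted p = 5.71e-22), naive follicular genes 15 of 17 higher and 2 not passing (16 adjusted over the list alone, median 4.33, adjusted p = 1.05e-15), and unfolded protein response genes 36 of 44 lower and 8 not passing (38 adjusted over the list alone, median -2.94, adjusted p = 1.23e-44). Granulocyte and macrophage markers were higher in memory (7 of 15, 8 not passing, 8 adjusted over the list alone, median 4.82, adjusted p = 9.14e-05), with Csf1r at 154 ± 113 against 5.27 CPM (4.82, adjusted p = 0.00368). Set 3 alone, with 1 spleen plasma library, gave 460 calls (30% higher) and set 4 alone 984 (38.2% higher), and 28 of the 1371 genes had the opposite sign in set 3, where the lone library is assumed to vary like the other groups. Only the libraries compared gave 735 calls and summed libraries 512. On FPKM by limma 81.6% of calls were higher, against 47.8% here, with the median of all genes at 0.627.

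Against bone marrow plasma cells 843 genes were higher and 919 lower in memory. Mt2, a metal-binding metallothionein, stood at 0.963 ± 0.224 CPM in memory and 1647 ± 794 CPM in bone marrow plasma cells (SD, n = 4 and 6, -10.71, SE 0.44, adjusted p = 1.47e-15). Ccr10, which homes plasma cells to mucosa and marrow (-9.28, adjusted p = 5.6e-08) and Igj (-4.12, adjusted p = 4.86e-17) were lower. Cd19 (5.34, adjusted p = 1.68e-10), Spib (7.35, adjusted p = 2.85e-11) and Ccr7 (8.20, adjusted p = 2.17e-06) were higher, and so were 20 of 26 B cell identity genes (median 2.82, adjusted p = 1.3e-30). Of 44 unfolded protein response genes 34 were lower, 1 higher and 9 did not pass (median -2.38, adjusted p = 5.09e-31). Il9r did not pass (35.7 ± 42.4 and 27.2 ± 18.4 CPM, 0.09, SE 0.94, adjusted p = 0.97). On FPKM by limma 82.5% of calls were higher, against 47.8% here, with the median of all genes at 0.706. Set 3 alone gave 1118 calls (47.6% higher) and set 4 alone 967 (37.8% higher), and summed libraries gave 539.

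Between bone marrow and spleen plasma cells 13 genes were higher and 13 lower in marrow, and on simulated data 24% of genes with a log2 fold change of 2 were found. Mt2 rose from 147 ± 47.4 CPM in spleen to 1647 ± 794 CPM in marrow (SD, n = 4 and 6, 3.27, SE 0.30, adjusted p = 2.62e-07), and Mt1, a second metallothionein, by 2.98 (adjusted p = 0.00276). Itgb7, an integrin chain of mucosal homing, rose from 11.3 ± 9.36 to 166 ± 21 CPM (3.84, SE 0.57, adjusted p = 0.000785). Pdia4, a folding enzyme of the endoplasmic reticulum, fell from 653 ± 145 to 38.7 ± 18.9 CPM (-4.06, SE 0.44, adjusted p = 4.26e-06), and the class II peptide editor gene H2-Ob fell by 1.96 (adjusted p = 0.00151). B2m fell by 1.05 (adjusted p = 3.6e-05). All 6 marrow libraries lay on 1 side of the 4 spleen libraries for these 6 genes. Il9r averaged 27.2 ± 18.4 CPM in marrow against 0.868 ± 1.14 CPM in spleen, with 5 of 6 marrow libraries above each spleen library, without passing (5.24, SE 1.22, adjusted p = 0.0683). Sdc1 (0.37, adjusted p = 0.959) and Prdm1 (-0.24, adjusted p = 0.989) did not pass. Unfolded protein response genes stood lower in marrow (0 higher, 1 lower, 43 not passing, 8 lower adjusted over the list alone, median -0.40, adjusted p = 9.59e-09). Stroma and endothelium markers stood higher (0 of 9 passing, 6 adjusted over the list alone, median 6.87, adjusted p = 0.00393, and adjusted p = 0.182 with an estimated correlation). The stromal chemokine gene Cxcl12 was at 400 ± 579 against 0.724 CPM (9.05, adjusted p = 0.0648), with 415 to 1490 CPM in the marrow libraries of set 4 and at most 1.59 CPM in those of set 3, and passed without spleen library 3-1 (adjusted p = 2.83e-06). The 26 calls became 17 without marrow library 3-1, 3-3 or 4-1, 16 without 4-3, and 15 and 17 without spleen library 4-1 and 4-2. Set 3 alone, with 1 spleen library that is assumed to vary like the other groups, gave 34 calls, 20.6% of them higher, and set 4 alone 27, 77.8% higher. Only the libraries compared gave 114 calls and summed libraries 0.

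The SRBC mice given IL-9 or anti-IL-9 were compared with PBS mice to ask for acute effects on each subset. In GC-MP cells 1 gene rose and 4 fell after IL-9. Apitd1, a centromere and DNA repair gene, fell from 51.8 ± 14.1 to 23.4 ± 3.9 CPM (SD, n = 6 each, -1.15, SE 0.18, adjusted p = 0.00114), with all 6 libraries below. Nt5c3 (-0.78, adjusted p = 0.0207), Rbm3 (-0.79, adjusted p = 0.0477, 4 of 6 libraries below) and Dbi (-0.76, adjusted p = 0.049) fell, and 1300014I06Rik, named after its values were seen, rose by 0.86 (adjusted p = 0.0207). With 1 library left out, Nt5c3 did not pass without PBS library 1-1 or 1-2 (adjusted p = 0.0774 and 0.0738) or IL-9 library 2-1, 2-2 or 2-3 (0.0915, 0.083 and 0.0648). Rbm3 did not pass without PBS library 1-1, 1-2 or 1-3 (0.0719, 0.148 and 0.167), or any IL-9 library (0.0808, 0.0668, 0.0732, 0.1, 0.112 and 0.0916 from 1-1 to 2-3). Dbi did not pass without PBS library 1-1, 1-2, 1-3 or 2-2 (0.0719, 0.148, 0.205 and 0.0718), or IL-9 library 1-2, 2-1, 2-2 or 2-3 (0.0563, 0.138, 0.236 and 0.0876). 1300014I06Rik did not pass without PBS library 1-1, 1-2, 1-3 or 2-2 (0.0719, 0.0738, 0.0888 and 0.0652), or IL-9 library 2-1, 2-2 or 2-3 (0.0823, 0.119 and 0.0876). Cish, a feedback inhibitor induced by STAT5, averaged 7.16 ± 3.91 against 1.78 ± 1.7 CPM with 4 of 6 libraries above, and did not pass (1.95, SE 0.86, adjusted p = 0.538). Il9r (0.18, adjusted p = 0.978), Bcl2 (0.06, adjusted p = 0.987), Cd38 (0.20, adjusted p = 0.971) and Aicda (-0.41, adjusted p = 0.49) did not pass, nor did the gamma-chain signalling list (0 of 26 passing, adjusted p = 0.337). The germinal centre program (-0.28, adjusted p = 0.000668), interferon response (-0.35, adjusted p = 0.00859), oxidative phosphorylation (-0.16, adjusted p = 1.64e-05) and ribosomal lists (-0.10, adjusted p = 0.00321) stood lower and had adjusted p = 0.261, 0.579, 0.244 and 0.935 with an estimated correlation. Without any 1 of GC-MP IL-9 libraries 2-1, 2-2 and 2-3 or PBS libraries 1-1 and 1-2 the 5 calls became 1, and without PBS library 1-3 they became 2. Set 1 alone gave 3 calls, none of them shared, and set 2 alone 102, with 4 shared. With libraries summed by group and set, 0 genes passed in each of the 6 comparisons of treatments.

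In GC-MPP cells 0 genes rose and 1 fell after IL-9 by edgeR (618 at an unadjusted p under 0.05, 11 by DESeq2 and 0 by limma). That gene, Dcun1d5, fell from 137 ± 27 to 71.7 ± 14.2 CPM (SD, n = 6 each, -0.94, SE 0.16, adjusted p = 0.00525), with all 6 libraries below. It also fell after anti-IL-9, so high levels in the shared PBS libraries stay open as the cause. Without IL-9 library 1-2 there were 2 calls, and set 1 alone gave 3 and set 2 alone 16, with Dcun1d5 in neither. Il9r did not pass (-0.37, adjusted p = 0.982). Interferon response genes stood lower (median -0.50, adjusted p = 0.000139, and adjusted p = 0.336 with an estimated correlation). The difference between the IL-9 effects on the 2 subsets passed for 0 genes by edgeR (381 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma), and its value was 0.54 for Il9r (SE 0.91, adjusted p = 0.999) and 3.93 for Cish (SE 1.63, adjusted p = 0.999). Without 1 library these ran from -0.34 (GC-MPP PBS 1-2) to 1.11 (GC-MPP IL-9 1-3) for Il9r and from 1.95 (GC-MPP PBS 2-1) to 5.61 (GC-MPP IL-9 2-3) for Cish.

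After anti-IL-9, 28 genes rose and 34 fell in GC-MP cells. The mice given anti-IL-9 and PBS may differ in genotype, as weighed below for LOC100504404, and the treatment was not tested apart from that. This limit holds for every comparison with anti-IL-9. Hmbs, an enzyme of haem synthesis, rose from 40.7 ± 6.95 to 72.7 ± 8.82 CPM (SD, n = 6 each, 0.85, SE 0.16, adjusted p = 0.00502). Rps29, a ribosomal protein gene, fell from 1016 ± 335 to 514 ± 130 CPM (-0.98, SE 0.16, adjusted p = 0.000496), and Rps15 (-0.78, adjusted p = 0.00357) and Rpl37a (-0.97, adjusted p = 0.00123, 4 of 6 libraries below) fell too. The ribosomal list had 11 of 78 lower and 67 not passing (6 higher and 31 lower adjusted over the list alone, median -0.20, adjusted p = 1.73e-08, and adjusted p = 0.742 with an estimated correlation). Hnrnpk, an RNA-binding protein gene, rose by 0.68 (adjusted p = 0.00996) and H2-K1 by 0.63 (adjusted p = 0.00598, 4 of 6 libraries above). Hmbs, Rps29, Rps15 and Hnrnpk were beyond all PBS libraries in 6 of 6. Bcl6 fell from 12.4 to 3.99 CPM (-1.68, SE 0.38, adjusted p = 0.0232), with no library below all PBS libraries, and had adjusted p = 0.0524 and 0.0876 without PBS library 1-3 and 2-2, and 0.0649, 0.0675, 0.0517 and 0.0539 without anti-IL-9 library 1-1, 1-2, 2-1 and 2-2. Rbm38 rose by 1.34 (adjusted p = 0.0126, 4 of 6 libraries above) and had adjusted p = 0.052 without PBS library 1-1, 0.0726 without PBS library 1-3 and 0.0704 without anti-IL-9 library 1-2. Il9r (0.25, adjusted p = 0.94), Bcl2 (0.13, adjusted p = 0.947) and Cd38 (-0.04, adjusted p = 0.989) did not pass. The 62 calls became 28 and 34 without PBS library 1-3 and 2-2, and 31 and 23 without anti-IL-9 library 1-1 and 1-2. Set 1 alone gave 52 higher and 68 lower, and set 2 alone 0 higher and 7 lower. On FPKM by limma 60.6% of calls were higher, against 45.2% here.

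LOC100504404, whose gene number the reference lists as H2-Ea, the alpha chain of the class II molecule I-E, fell in both subsets after anti-IL-9. It fell from 2044 ± 532 to 257 ± 280 CPM in GC-MP (SD, n = 6 each, -3.62, SE 0.77, adjusted p = 0.0188) and from 1925 ± 745 to 20.6 ± 19.2 CPM in GC-MPP cells (-7.04, SE 0.90, adjusted p = 3.59e-05), below all PBS libraries in 6 of 6. The sets differed: in GC-MP cells the anti-IL-9 libraries were at 3.76 ± 1.84 CPM in set 1 and 511 ± 57.9 CPM in set 2 (SD, n = 3 each). The gene also separated untreated libraries, at 10.6 ± 1 CPM in set 1 and 1830 ± 352 CPM in set 2 of the NP GC-MP group (SD, n = 3 each).

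**Figure D4:**
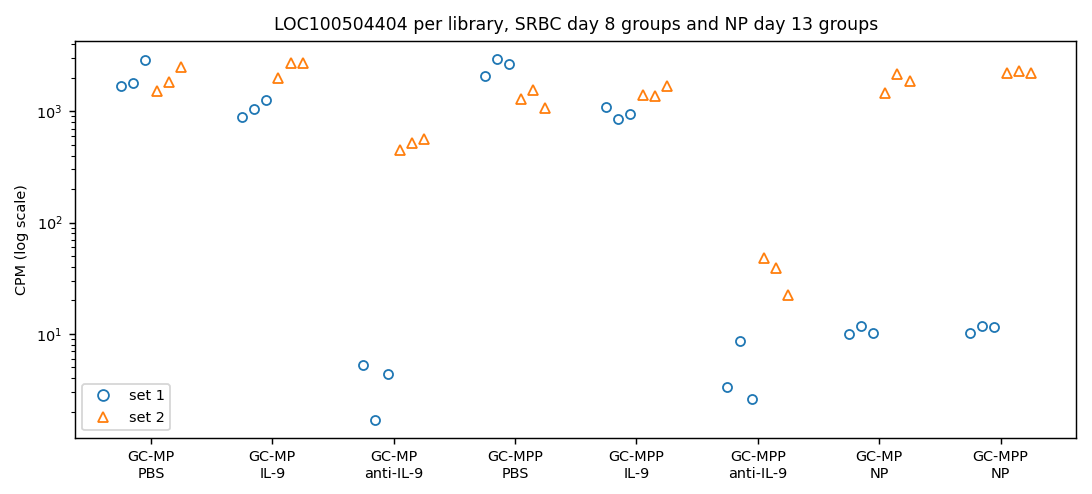
CPM of LOC100504404 on a log scale in each library of the 6 SRBC groups and the 2 NP GC groups. Circles are set 1 and triangles set 2; NP libraries of set 1 lay near 10.6 CPM and those of set 2 near 1830 CPM in GC-MP cells.

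In GC-MPP cells 8 genes rose and 12 fell after anti-IL-9. Ltb, which encodes the lymphoid tissue cytokine lymphotoxin beta, fell from 583 ± 117 to 338 ± 47.6 CPM (SD, n = 6 each, -0.78, SE 0.12, adjusted p = 0.000223), and Dcun1d5 (-0.86, adjusted p = 0.00344) and Zzef1 (-1.06, adjusted p = 0.00156) fell. H2-K1 rose by 0.61 (adjusted p = 0.0137, 3 of 6 libraries above) and the replication origin gene Orc6l by 1.27 (adjusted p = 0.0137). Without PBS library 1-2 both had adjusted p = 0.0848, without anti-IL-9 library 1-1 H2-K1 had 0.088, and without anti-IL-9 library 2-3 Orc6l had 0.0536. Il9r did not pass (-0.01, adjusted p = 0.999). Interferon response genes stood lower (0 of 33 passing, 5 adjusted over the list alone, median -0.69, adjusted p = 2.28e-06, and adjusted p = 0.108 with an estimated correlation). Of the sets, set 1 alone gave 13 calls and set 2 alone 8. The 20 calls became 9 without PBS library 1-2 and 11 without anti-IL-9 library 2-3. The difference between the anti-IL-9 effects on the subsets passed for 0 genes by edgeR (469 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma), with -0.90 for Rps29 (SE 0.22, adjusted p = 0.791), -1.43 for Bcl6 (SE 0.52, adjusted p = 0.999) and 0.26 for Il9r (SE 0.92, adjusted p = 0.999, from -0.567 without GC-MPP PBS library 1-2 to 1.26 without GC-MPP anti-IL-9 library 1-1).

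Set directly against anti-IL-9, IL-9 gave 2 genes higher and 2 lower in GC-MP cells: Rps29 (0.75, SE 0.16, adjusted p = 0.0411, 6 of 6 libraries above), Gm10260 (1.33, adjusted p = 5.22e-05), Hmbs (-0.80, SE 0.16, adjusted p = 0.0411, 6 of 6 below) and 2610301G19Rik (-1.48, adjusted p = 0.0411). Gm10260 and 2610301G19Rik were named after their values were seen. With 1 library left out, Rps29 passed only without anti-IL-9 library 1-1 or 2-2, and its adjusted p was 0.0628, 0.0578, 0.0566, 0.0994, 0.0896 and 0.19 without the IL-9 libraries from 1-1 to 2-3 and 0.172, 0.143, 0.0937 and 0.0758 without anti-IL-9 library 1-2, 1-3, 2-1 and 2-3. Hmbs had 0.0692, 0.128, 0.0896 and 0.19 without IL-9 library 1-2, 2-1, 2-2 and 2-3, and 0.0944, 0.127, 0.0867, 0.05 and 0.0758 without anti-IL-9 library 1-1, 1-2, 1-3, 2-2 and 2-3. 2610301G19Rik had 0.193, 0.203 and 0.225 without IL-9 library 2-1, 2-2 and 2-3, and 0.127, 0.133, 0.077, 0.0631 and 0.0758 without anti-IL-9 library 1-2, 1-3, 2-1, 2-2 and 2-3. The count of 4 became 1 without IL-9 library 2-1 or 2-3 or anti-IL-9 library 1-2, 1-3 or 2-3, and 2 without IL-9 library 1-2 or 2-2 or anti-IL-9 library 2-2. Set 1 alone gave 8 calls and set 2 alone 159. In GC-MPP cells 7 genes were higher and 0 lower by edgeR (737 at an unadjusted p under 0.05, 14 by DESeq2 and 8 by limma), among them LOC100504404 (6.09, SE 0.85, adjusted p = 0.000237), the vesicle coat gene Sec24c (0.98, SE 0.17, adjusted p = 0.00209) and Ltb (0.65, SE 0.12, adjusted p = 0.00468). H2-Q2 (3.35, adjusted p = 0.00468) and Gm10499 (4.71, adjusted p = 0.000237), named after their values were seen, were also among them. Ltb, H2-Q2 and Gm10499 lie within 5 Mb of H2-Ea. Mice that differ there, weighed below, may account for these calls, which was not tested apart from the treatment. Set 1 alone gave 6 calls, 5 of them shared, and set 2 alone 79, 6 of them shared. The IL-9 and anti-IL-9 effects correlated across genes with r = 0.53 in GC-MP cells, where simulated libraries with no effect and the same shared PBS group gave 0.52 (0.502 to 0.536 in 20 simulations), and with r = 0.567 against 0.531 (0.514 to 0.558) in GC-MPP cells, above every simulation. The covariances, 0.12 and 0.157, also lay above the simulated ones (0.0864 to 0.0964 and 0.09 to 0.104). Genes are not independent replicates, and with the PBS libraries split between the effects the correlations averaged 0.0489 (from -0.0908 to 0.0817) and 0.0588 (from -0.0919 to 0.107).

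The genes higher and lower in GC-MP after NP-KLH were read in these contrasts to ask whether IL-9 moved cells along that axis. For IL-9 against anti-IL-9 their medians were 0.14 and -0.10 in GC-MP cells and 0.19 and -0.09 in GC-MPP cells, with 0 members passing by edgeR. Camera's adjusted p was at most 0.000686 with its preset correlation, and with an estimated correlation adjusted p = 0.537 and 0.376 in GC-MP and 0.504 and 0.376 in GC-MPP cells. For IL-9 against PBS the medians were 0.14 and -0.15 in GC-MP cells (adjusted p = 0.000978 and 2.59e-07, and 0.537 and 0.197 with an estimated correlation) and 0.07 and -0.11 in GC-MPP cells (adjusted p = 0.0421 and 5.74e-05, and 0.696 and 0.357 with an estimated correlation). For anti-IL-9 against PBS they were 0.01 and -0.07 in GC-MP cells (adjusted p = 0.892 and 0.138) and -0.085 and -0.00728 in GC-MPP cells (adjusted p = 0.0843 and 0.892) with the preset correlation, so none of these 4 passed.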

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

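The plasma share test, and the reading of H2-Ea in untreated groups, were chosen after their results had been seen; the lower limit on low-baseline members in the macrophage test for NP-KLH was added then too. Of 110 groups of values tested for 1 library apart from the rest, 15 had one, where chance gives about 1 in 20, or 5.5. Number of genes detected was 11000 in GC-MPP anti-IL-9 library 1-2 and 11900 to 12400 in the others of its group. Bcl2 was at 137 CPM in GC-MP PBS library 2-2 (57.5 to 81.6 in the others), at 21.2 CPM in GC-MPP PBS library 1-3 (1.65 to 7.67) and at 0.624 CPM in NP GC-MPP library 2-3 (7.8 to 10.4). NP GC-MPP library 1-1 had 36.9 CPM of Il9r (0.292 to 6.06) and 10.1 CPM of S1pr1 (0.769 to 1.86), library 1-2 of that group 11.7 CPM of Sell (1.05 to 2.96) and library 2-1 30.5 CPM of Klf2 (2.45 to 12), while NP GC-MP library 1-1 had 358 CPM of Sell (183 to 217). Spleen plasma library 3-1, the 1 of its group in set 3, had 139 CPM of Cd19 (35.3 to 52.2), 43.3 CPM of Spib (0.99 to 4.14) and 217 CPM of Mt2 (118 to 133). Rps29 was at 1680 CPM in GC-MP PBS library 2-2 (796 to 1000), Dcun1d5 at 44 CPM in GC-MPP IL-9 library 1-3 (72.6 to 84.5), and Cxcl12 at 1490 CPM in bone marrow plasma library 4-1 (0.475 to 492).

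The IL-9 effect differed between GC-MP and GC-MPP, by the test of the difference with a preset correlation, for the germinal centre program (median difference -0.196), light zone activation (0.217), G2 and M phase (-0.178), oxidative phosphorylation (-0.143) and ribosomal proteins (-0.113). The anti-IL-9 effect differed for ribosomal proteins (-0.247). None of these 6 passed with an estimated correlation.

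Macrophage transcripts outside the fixed marker list stood higher in GC-MP than in GC-MPP cells among NIP-binding libraries, and moved both ways after SRBC and NP-KLH. In NIP-binding cells the median log2 fold change of 15 such transcripts was 2.77, with 14 positive and quartiles from 1.96 to 5.5, which macrophages or their RNA would give. Across the 18 GC-MP SRBC libraries the 11 transcripts measured there correlated weakly, but more than random genes (mean pairwise correlation 0.124, against a 95th percentile of 0.067 for random genes). Such correlation was not measured in the NIP-binding libraries. After SRBC the median was 0.745 with quartiles from -0.0966 to 3.12, 8 of 11 positive and 6 passing, among them Tyrobp at 4.18, Fcer1g at 5.40 and Spic at 6.59 from low baselines and Apoe at -0.69 and Lgmn at -0.43 from 344 and 165 CPM, and after NP-KLH -0.0423 over 6 members (3 positive, 1 passing), which leaves both open: the bound set beforehand assumed low baselines, but in NP GC-MPP cells Apoe stood at 448, Lgmn at 189, Ctsb at 88.5 and Sirpa at 27.8 CPM, where a small share would not show, while Tyrobp rose by 3.75. Tyrobp stood at 411, Apoe at 505 and Ctsb at 539 CPM in NIP-binding GC-MP cells. GC-MP cells were gated as GL7-, FAS- and CD38-positive, and how far these gates kept out free macrophages was not tested. Free macrophages, attached macrophage fragments, taken-up RNA and B cell expression of some of these genes were not told apart.

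Plasma cell transcripts stood in memory libraries at a median of 3.07% of their spleen plasma level over 25 genes (quartiles 0.655% and 4.64%), and Igj at 5.43%. If plasma cells alone brought them, all would share Igj's percentage, but 11 of 25 lay under 2.71%, and per library the medians were 0.703%, 2.11%, 0.47% and 0.383% against 3.23%, 5.14%, 7.15% and 6.19% for Igj. A share of plasma cells could still carry part of the rise of Prdm1, Igj and Sdc1, although the gate kept CD19-positive cells, and low expression by memory cells stays open; the percentage condition was tightened after the result was seen, so the test decides neither.

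LOC100504404 (H2-Ea) was lower after anti-IL-9, in set 1 near 0 in both subsets. In set 2 it was at 511 CPM in GC-MP and 36.4 CPM in GC-MPP (1960 and 1300 with PBS). Mice with and without an expressed H2-Ea allele, unevenly spread over treatments, may be the cause, since C57BL/6, the stated strain, carries an untranscribed allele. This alone would not give the set 2 gap if both subsets came from the same mice. Untreated NP GC-MPP libraries differed between sets by a log2 of 7.57 (7.36 in GC-MP), without any antibody. Libraries given PBS differed by -0.971 (-0.113 in GC-MP). H2-Aa was at 4650 and 2050 CPM in sets 1 and 2 of the NP GC-MPP group, past a limit set afterwards. It is itself called between those sets and within 5 Mb of H2-Ea, so that limit cannot count against the allele. For treated mice these levels alone do not decide. Of genes within 5 Mb 21 of 127 (16.5%) had p under 0.05 for anti-IL-9 against PBS in GC-MPP, against 10.1% elsewhere (ratio 1.63, Fisher's exact p = 0.0175), and 5 of the 14 called genes with a position lay there (0.208 expected); in GC-MP the ratio was 1.46 (exact p = 0.055) with 1 of 55 called genes there (0.816 expected, exact p = 0.562), for IL-9 in GC-MPP 1.02 (exact p = 0.53), and between the sets of the untreated NP libraries 1.95 (31.5% against 16.1%, exact p = 2.08e-05, 13 called genes there and 4.6 expected). Reads moving to a near-identical transcript are argued against, since 0% of 987 words of 50 bases of H2-Ea occur in transcripts of other genes. An effect of anti-IL-9 on this gene stays open but was not tested apart from the mice. The calls of the linked H2-K1, Ltb, H2-Q2, Gm10499 and Nrm carry the same limit. So do the other anti-IL-9 calls, since mice that differ here may differ elsewhere.

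Other splits of the same libraries were fitted for each comparison of at least 3 libraries per group, 100 splits where more exist. If libraries of 1 set are independent samples, which the labels do not say, chance can be excluded for GC-MP against GC-MPP after NP-KLH (388 calls, 1 split as large, highest other 7) and after SRBC (1281, 1, 273), memory against spleen plasma cells (1371, 1 of 35 splits, 8) and bone marrow plasma cells (1762, 1, 120), bone marrow against spleen plasma cells (26, 1, 9), and anti-IL-9 against PBS in GC-MP (62, 1, 19). With libraries summed by group and set, a fit with few residual degrees of freedom, there were 0 calls after NP-KLH, for bone marrow against spleen plasma cells and for all treatment comparisons, so for these the exclusion rests on that condition, and 320 after SRBC and 512 and 539 for memory against spleen and bone marrow plasma cells. The split that follows the set gave 208 calls after NP-KLH, 13 after SRBC and 4 for anti-IL-9 in GC-MP. For IL-9 against PBS in GC-MP (5 calls) 2 of 100 splits were as large, highest other 7, which alone would exclude chance, but the split by set gave 68, and the same holds for anti-IL-9 against PBS in GC-MPP (20 calls, 1 split as large, highest other 4, by set 72); for IL-9 against anti-IL-9 2 of 100 were as large in both subsets (4 and 7 calls), the other being the split by set with 256 and 90. These point to a structure of the libraries by set larger than the treatments, and the sets alone gave 3 and 102, 13 and 8, 8 and 159, and 6 and 79 calls, in that order of comparisons. For IL-9 against PBS in GC-MPP (1 call, 20 of 100 splits as large, highest other 4, by set 62) and for both differences of effects (0 calls, 100 of 100, highest other 9 and 1, by set 98 and 65) chance cannot be excluded.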

How the results depend on the processing

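Leaving out both memory libraries of set 4, and the memory list without plasma cell genes, were chosen after the results were seen; all other alternatives were planned. The number of calls stayed within 1.5 times its value in 266 of 397 recomputed counts, among them all 18 with RLE factors. No named gene, list or signature changed direction past its threshold in the alternatives run; of 4742 values of named genes under alternatives 407 no longer passed and 19 newly passed, and of 838 list tests 68 no longer passed, 66 of them with an estimated correlation, and 2 newly passed. On FPKM 7 of 36 counts with another pseudocount or no minimum moved. Except where stated, the cause was not tested. Depth limits the genes with few counts in libraries such as the GC-MP PBS ones of set 2 (1.12 to 1.75 M), and the NIP-binding GC groups had 2 libraries each.

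DESeq2 called more genes: 686 for GC-MP against GC-MPP after NP-KLH, 151 in NIP-binding cells, 531 and 154 for memory against GC-MPP and GC-MP, 1284 and 998 for spleen plasma cells against GC-MPP and GC-MP, 2213 for memory against spleen plasma cells, 150 for bone marrow against spleen plasma cells, 35 and 11 for IL-9 against PBS in GC-MP and GC-MPP, 153 and 70 for anti-IL-9 against PBS, and 26 and 14 for IL-9 against anti-IL-9. On simulated data 16.2% of its calls were false in the NP comparison, 37.3% for bone marrow against spleen plasma cells and 7.18% for anti-IL-9 against PBS in GC-MP. With limma on FPKM the counts were 51 in NIP-binding cells, 360 and 53 for memory against GC-MPP and GC-MP, 2015 and 1707 for spleen plasma cells against both, 2789 and 3480 for memory against spleen and bone marrow plasma cells, 1 and 0 for IL-9 against PBS in GC-MP and GC-MPP, 99 and 38 for anti-IL-9 against PBS and 10 for IL-9 against anti-IL-9 in GC-MP. No filter on low counts gave 82 in NIP-binding cells, 313 and 58 for memory against GC-MPP and GC-MP, 98 for bone marrow against spleen plasma cells and 2 for IL-9 against anti-IL-9 in GC-MP. An average logCPM of at least 4 gave 12 for IL-9 against PBS in GC-MP and 4 for IL-9 against anti-IL-9 in GC-MPP.

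Without the set term there were 247 calls after NP-KLH, 1 for IL-9 against PBS in GC-MP, 22 and 12 for anti-IL-9 against PBS in GC-MP and GC-MPP and 1 for IL-9 against anti-IL-9 in GC-MP. Libraries summed by group and set, which leaves 1 sample per group and set and few residual degrees of freedom, gave 0 after NP-KLH, 1 in NIP-binding cells, 320 after SRBC, 14 and 4 for memory against GC-MPP and GC-MP, 330 and 219 for spleen plasma cells against both, 512 and 539 for memory against spleen and bone marrow plasma cells, and 0 for bone marrow against spleen plasma cells and for all 6 comparisons of treatments. Set 1 alone gave 111 after NP-KLH, 255 after SRBC, 3 and 3 for IL-9 against PBS in GC-MP and GC-MPP, 120 and 13 for anti-IL-9 against PBS and 8 for IL-9 against anti-IL-9 in GC-MP. Set 2 alone gave 32 after NP-KLH, 102 and 16 for IL-9 against PBS, 7 and 8 for anti-IL-9 against PBS, 159 and 79 for IL-9 against anti-IL-9 and 1 for the difference of anti-IL-9 effects. Set 3 alone gave 55 in NIP-binding cells, 198 and 30 for memory against GC-MPP and GC-MP and 460 and 1118 for memory against spleen and bone marrow plasma cells, and set 4 alone 967 for the last. Only the libraries compared in the fit gave 5 in NIP-binding cells, 9 and 2 for memory against GC-MPP and GC-MP, 358 for spleen plasma cells against GC-MP, 735 for memory against spleen plasma cells, 114 for bone marrow against spleen plasma cells, 9 and 3 for IL-9 against PBS, 51 for anti-IL-9 against PBS in GC-MPP and 12 and 11 for IL-9 against anti-IL-9; all 30 libraries of the table in the NP fit gave 213. Without both memory libraries of set 4 there were 217 and 33 calls for memory against GC-MPP and GC-MP and 1135 against bone marrow plasma cells.

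The full library number as a block gave 309 calls after NP-KLH, 285 of them shared, 15 calls for bone marrow against spleen plasma cells, 3 for IL-9 against PBS and 36 for anti-IL-9 against PBS in GC-MP, and 1 for IL-9 against anti-IL-9 in GC-MP. The condition for pairing, a correlation over 0.1 in every same-number pair, was not met: with group means removed, same-number libraries correlated between 0.0516 and 0.139 after NP-KLH (3 of 6 pairs over 0.1), between -0.0203 and 0.0389 in sets 3 and 4 (0 of 23) and between -0.0197 and 0.165 after SRBC (17 of 90), and same-set libraries with other numbers averaged 0.0593, 0.0032 and 0.0721. After NP-KLH all 6 pairs were positive (mean 0.0916), so a weak link by number stays open there, and 9 of 12 libraries correlated best with their own number, against 4 of 17 and 12 of 36 in the others. The block also spends more degrees of freedom than the set.

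With 1 library left out the calls ranged from 241 to 399 after NP-KLH, 7 to 24 in NIP-binding cells, 1053 to 1291 after SRBC, 30 to 175 and 5 to 17 for memory against GC-MPP and GC-MP, 352 to 632 and 274 to 507 for spleen plasma cells against both, 1034 to 1380 and 1459 to 1667 for memory against spleen and bone marrow plasma cells, 15 to 21 for bone marrow against spleen plasma cells, 1 to 7 and 1 to 2 for IL-9 against PBS in GC-MP and GC-MPP, 23 to 69 and 9 to 27 for anti-IL-9 against PBS, and 1 to 5 and 7 to 10 for IL-9 against anti-IL-9. Where this leaves 1 sample in a group, that sample is assumed to vary like the other groups. With an estimated correlation the GC-MP signature no longer passed for IL-9 against PBS (medians 0.137 and -0.154 in GC-MP, 0.0667 and -0.112 in GC-MPP) and for IL-9 against anti-IL-9 (0.135 and -0.102, 0.194 and -0.0927). Its higher list for IL-9 against PBS in GC-MPP also no longer passed with the top 200 genes (0.0667) or without cell cycle genes (0.0641). The memory signature had medians of 1.49 and -0.555 without the memory libraries of set 4.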

Other observations

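These patterns were noticed after the values were seen. GC-MP libraries after SRBC combined lower S phase transcripts with some higher mitotic ones. Of the G2 and M phase list 9 rose and 5 fell after SRBC, with Cenpa at 1.28, Ccnb2 at 1.90 and Cdc20 at 2.49 against Top2a at -1.16, while 33 of 37 S phase genes fell, as the mKO2 gate selects. After NP-KLH 1 of 35 G2 and M phase genes rose and 1 fell (4 and 1 adjusted over the list alone). There 9 of 36 S phase genes fell. The experiments were not tested against each other. Both Aicda and S1pr2 remained abundant in GC-MP cells while S1pr1, Sell and Klf2 had risen, with log2 fold changes after NP-KLH of 5.86, 6.17 and 4.15 for the last 3 and -0.99 and -1.0 for the first 2.

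Il9r was not uniform in memory or plasma cells. It stood at 27.2 ± 18.4 CPM in bone marrow plasma cells and 0.868 ± 1.14 CPM in spleen plasma cells (SD, n = 6 and 4; 5.24, SE 1.22, adjusted p = 0.0683), and memory libraries averaged 35.7 ± 42.4 CPM.

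The memory libraries of set 4 had 9395 to 9823 genes detected and those of set 3 10754 to 10956, and totals of 2.49 to 3.72 against 4.75 to 4.82 M. The GC-MP libraries given PBS had 3.13 to 5.65 M counts in set 1 and 1.12 to 1.75 M in set 2. Cd36 had 3 counts over the 6 bone marrow plasma libraries and 314 over the 4 of spleen (adjusted p = 0.00128), and H2-Q2, linked to H2-Ea, averaged 0.283 CPM in set 1 of GC-MP anti-IL-9 libraries and 17.2 CPM in set 1 of PBS.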
